A study of Mus musculus with 11 samples.

How the data were processed

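The study measured RNA from microglia of the spinal cord of healthy female C57BL/6 mice in 11 samples. In RiboTag mice a Cre recombinase switches on a haemagglutinin tag on the ribosomal protein Rpl22, so that ribosomes, with the RNA bound to them, can be pulled down from the chosen cell type. Per the labels the Cre was Tmem119-CreERT2, a tamoxifen-dependent Cre active in microglia, and in the conditional knockout (cKO) the same Cre deleted Kdm6a, an X-linked gene for a histone H3K27 demethylase. The labels name 5 cKO samples (2, 4, 5, 6 and 7) and 6 wild-type (WT) samples (8, 9, 13, 15, 16 and 17). They give no batch. Nothing in them says in so many words that each sample came from a separate animal, so the p-values measure the spread between these samples. No pair of samples of one group had counts that agree within sampling noise (the most similar pair, WT8 and WT15, had a chi-square of 17.8 per gene). This argues only against the same library having been entered as 2 samples. It cannot tell 2 libraries of 1 animal from libraries of 2 animals. Each sample was counted as 1 replicate.

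Per the labels' protocols, RNA was purified with a Direct-zol kit and sequencing libraries were made with a stranded KAPA kit after mRNA enrichment. The submitters' processing notes name bcl2fastq 2.17, FastQC, Trimmomatic and the mouse build mm10. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here. The deposited table holds raw counts per Ensembl gene, 1 column per sample, for 39017 genes, with no normalization by the authors that the values show. Library totals ran from 28620584 to 40943004 counts. In each library 73.5 to 83.9% of the counts between 1 and 200 were even numbers, a share that would arise if both mates of a read pair were counted, in which case the number of independent fragments is about 50% of the counts. Gene symbols were found for 37607 of the identifiers in the gene name table supplied for the mouse, and coordinates are those of GENCODE M21, which uses the same assembly as mm10.

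Some rows of the table cannot be read as expression. A total of 17296 genes had a count of 0 in every library. These include contiguous stretches of the genome with almost no counts at all, among them chromosome 17 from 33773750 to 34719815 (52 of 53 protein-coding genes at 0, H2-K1 included), chromosome 17 from 48036745 to 48539714 (Trem2), chromosome 4 from 130360132 to 130955475 (Laptm5) and chromosome 16 from 18776847 to 19629916 (Cldn5). Genes there were treated as not measured. Of 80 ribosomal protein genes, 39 had a mean count under 200 and 4 a summed count of 0, so the ribosomal protein list is incomplete. Trp53bp1 ranked 2 by mean level, at 14038 CPM (counts scaled to a common library size), and Bcar1 ranked 9 at 8092 CPM. These levels are given as values only. The glycolysis genes Gapdh, Pgk1 and Pgam1, chosen after their values were seen, had an average log2 CPM of only 1.64, 2.73 and 0.74. Eno1 was too low to test, so the glycolysis list may be incomplete as well.

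Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 16025, and scaled by TMM factors. The main test was edgeR's quasi-likelihood F test with robust estimation, genotype as the only term and all 11 samples, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. CPM values are given as mean ± SD over libraries, and log2 CPM was computed with a prior count of 2. Comparisons of a single measure between genotypes used two-sided exact permutation tests over the 462 possible splits, with the smallest possible p at 0.00216.

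The design, the alternatives, the rule for named genes and 29 gene lists were fixed before the data were examined. The lists cover homeostatic and disease-associated microglia, 15 pathways and 12 other cell types that a spinal cord pulldown could carry. Each list was tested with limma's camera with the correlation between genes estimated per list, adjusted over the 29 lists; camera with a preset correlation of 0.01 and fry were alternatives. The named genes are Kdm6a; the 12 genes with the largest log2 fold change in each direction among those past the threshold with an average log2 CPM of at least 1, leaving out predicted and unnamed symbols; up to 4 members of each list past the threshold, by smallest p, or, where none passed, up to 2 by average expression, as values; and Uty as a check of sex. A total of 4 list members are not reported here by name, in text or figures, but stay in the list statistics. Other genes are named only where the text says that they were chosen after their values were seen.

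On counts simulated from these samples' means and library sizes (15517 genes, 200 of them changed, and 20 more changed 1.5-fold as a planted list), the same procedure recovered 34.3% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 84.8% of those changed 3-fold, and 5 of 130 calls in all were of genes left unchanged. The changed genes were drawn from those with a mean above 2 CPM, and the simulated counts held no shift shared by several libraries. These shares need not hold for genes of lower level or for the real libraries. Alternatives were DESeq2's size factors, library totals with no factor, no filter on low counts, a covariate for the markers of neurons, astrocytes and oligodendrocytes, non-robust estimation, a threshold of 0.1, a fold limit of 1.5, DESeq2 1.42.0, limma-voom with sample quality weights, and leaving out each sample in turn. Leaving out WT13, WT16 and WT17 together and halving the counts were added after seeing the data.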

Results

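RNA bound to tagged microglial ribosomes was compared between spinal cords labelled as a conditional knockout of Kdm6a in microglia (cKO, 5 samples) and wild-type spinal cords (WT, 6 samples), all from healthy females. The total count per sample was 33267791, 35459168, 29475447, 28620584 and 36259520 for cKO2, cKO4, cKO5, cKO6 and cKO7, and 36317220, 34774352, 40943004, 33588326, 32768942 and 32983519 for WT8, WT9, WT13, WT15, WT16 and WT17. The series title names the question as the effect of losing Kdm6a in microglia on the transcriptome of disease-associated microglia.

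Kdm6a (ENSMUSG00000037369, chromosome X, 18162575 to 18279936, plus strand, mm10) had 6.39, 7.31, 7.73, 6.29 and 3.80 CPM in cKO2, cKO4, cKO5, cKO6 and cKO7, against 12.03, 10.37, 7.46, 7.24, 10.37 and 10.08 CPM in WT8, WT9, WT13, WT15, WT16 and WT17. The group values were 6.31 ± 1.53 CPM (SD, n = 5) and 9.59 ± 1.87 CPM (SD, n = 6), and the ranges overlapped. The log2 fold change was -0.61 (SE 0.25, 95% interval -1.12 to -0.09), which did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.193). Counts are per gene, and the exons removed by the deletion are not given in the sources used here, so exons outside the deleted part count towards these values. Uty, the Y-linked paralog of Kdm6a, had 0 counts in every library, and another Y-linked gene, Ddx3y, had 2 counts in cKO6 and 0 elsewhere.

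**Figure D1:**
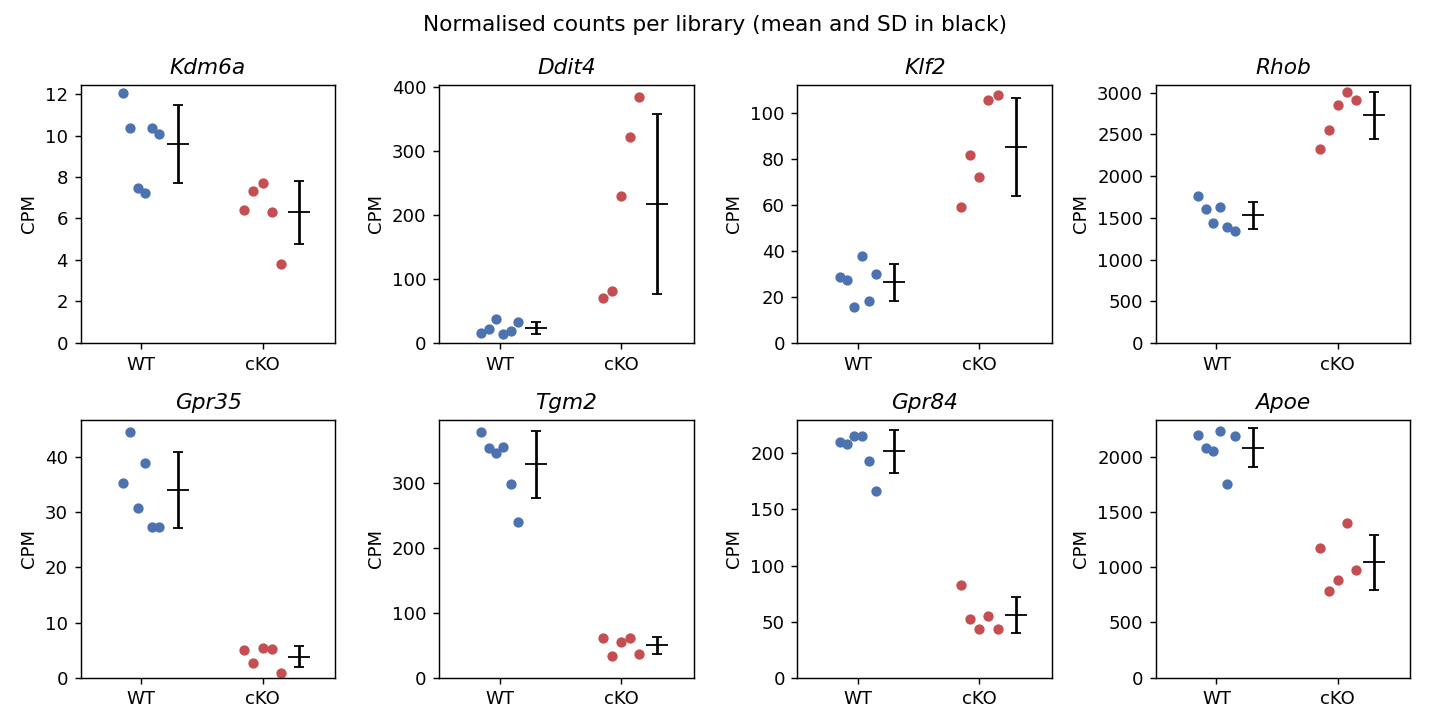
Normalised counts (CPM, linear axis from 0) of 8 genes in each library, WT in blue and cKO in red, with the mean and SD in black. Kdm6a overlaps between the genotypes, whereas the 5 cKO libraries lie on one side of the 6 WT libraries for the other 7 genes shown.

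Between the genotypes 687 of 16025 genes passed the threshold, 298 higher and 389 lower in cKO. Changes of large size were mostly decreases: 17 of the higher genes and 128 of the lower genes changed at least 2-fold. For 455 of the 687 genes every cKO library lay on one side of every WT library, which is likely for genes picked by a test on the same values. Over all genes tested this arrangement held for 4.16%, where chance gives 0.43%. With library totals in place of TMM factors the split was 203 higher and 601 lower, and the median log2 fold change of all genes moved from -0.013 to -0.098. Without WT13, WT16 and WT17, 164 genes were higher and 363 lower, and 392 of the 687 genes were shared.

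Among the 12 genes with the largest increases Ddit4, an inhibitor of mTORC1 signalling, rose 9.30-fold (217.4 ± 141 CPM in cKO, n = 5, against 23.35 ± 9.13 in WT, n = 6; log2 fold change 3.22, SE 0.52; edgeR adjusted p = 0.00894). Tsc22d3, the glucocorticoid-induced leucine zipper, rose 3.09-fold (SE 0.25 on the log2 scale; edgeR adjusted p = 0.00619). The Krüppel-like transcription factors among the 12 were Klf4 at a log2 fold change of 2.04 (SE 0.38) and Klf2 at 1.69 (SE 0.22). The others were Minar1 (1.82), Efnb2, a membrane-bound ligand of Eph receptors (1.6), Ston1 (1.53), the Src-family kinase Yes1 (1.42), the Myc-family gene Mycl (1.40), Fam72a (1.39), Gpr165 (1.35) and Dact1 (1.30). Ddit4, Klf4, Tsc22d3 and Mycl no longer passed without WT13, WT16 and WT17, with edgeR adjusted p of 0.0779, 0.0548, 0.0935 and 0.151, at log2 fold changes of 3.65, 2.27, 1.42 and 1.17. Minar1 did not pass without cKO4 or cKO5 (edgeR adjusted p = 0.0798 and 0.0511), nor Yes1 without cKO5 (0.0662).

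Among the 12 genes with the largest decreases Gpr35, an orphan G protein-coupled receptor, fell 8.97-fold, from 34.02 ± 6.91 CPM in WT (n = 6) to 3.81 ± 1.97 CPM in cKO (n = 5; log2 fold change -3.16, SE 0.36; edgeR adjusted p = 8.17e-05). Tgm2, a transglutaminase, fell 6.62-fold, from 329.2 ± 51.5 to 49.74 ± 13.7 CPM (log2 fold change -2.73, SE 0.19; edgeR adjusted p = 1.15e-06). Ebi3, a subunit of interleukin-27 and interleukin-35, had a log2 fold change of -2.56 (SE 0.23), the sialic acid receptor Siglecf -2.33 (SE 0.21), the Fc receptor Fcgr4 -2.24 (SE 0.28) and the cytokine Tnfsf8 -3.07 (SE 0.58). AB124611 was at -2.88. BC147527 (-4.80, SE 1.07) was at 0 in cKO4, cKO6 and cKO7, moved to -8.13 without cKO5, and did not pass without cKO2 (edgeR adjusted p = 0.0618) or without the 3 WT libraries (0.0852). Slc2a4rg-ps, a pseudogene (-2.75), Pstpip1 (-2.74), Myh6 (-2.36) and Ifit3b (-2.34), a close copy of Ifit3, also passed, but none of them did without WT13, WT16 and WT17, with edgeR adjusted p of 0.666, 0.109, 0.709 and 0.15 at log2 fold changes of -1.10, -2.59, -1.28 and -2.08. Reads of Ifit3b can be shared with Ifit3.

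**Figure D2:**
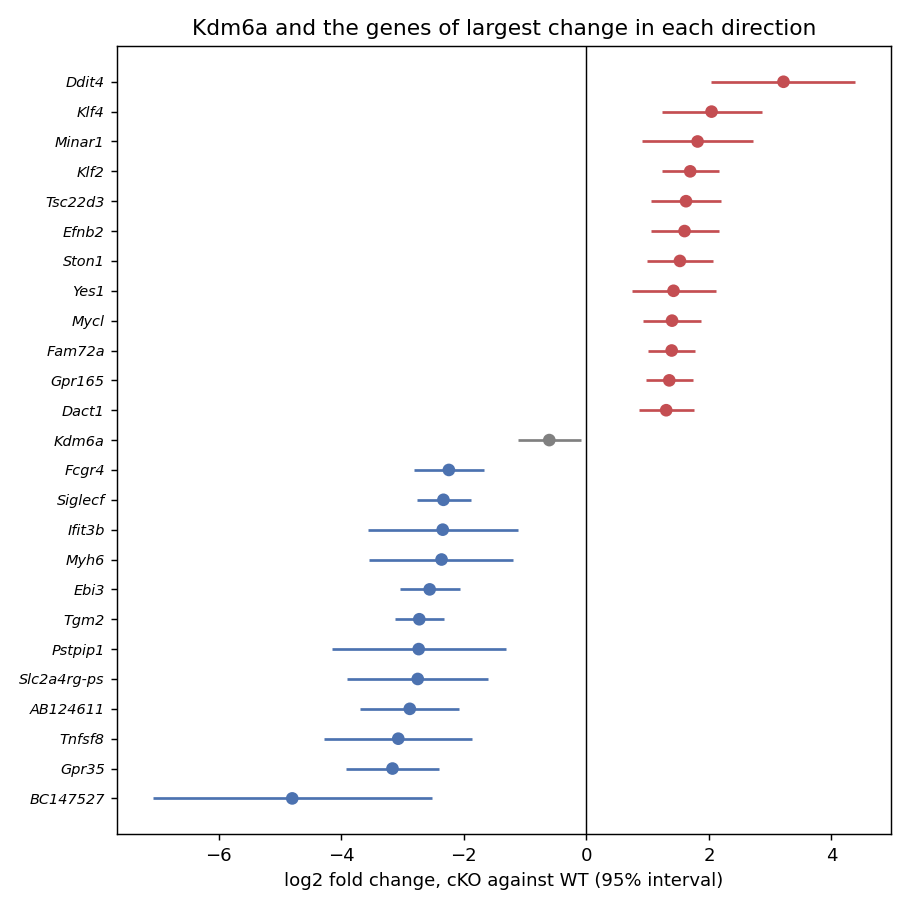
Log2 fold change of cKO against WT, with its 95% interval, for Kdm6a (grey, not past the threshold) and the 12 genes of largest change in each direction (red higher, blue lower). Ddit4 has the highest value at 3.22 and BC147527 the lowest at -4.80, with the widest interval.

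Of 21 measured genes of the homeostatic microglia list, 13 were higher and 2 lower in cKO, and 6 did not pass; adjusted over the list alone, 16 were higher and 2 lower. The list as a whole did not pass limma's camera test with an estimated correlation (adjusted p = 0.66), and with a preset correlation the adjusted p was 4.5e-07. Rhob, a small GTPase, rose from 1528 ± 162 CPM (n = 6) to 2728 ± 282 CPM (n = 5; log2 fold change 0.84, SE 0.08), and Cst3, a cysteine protease inhibitor, by a log2 fold change of 0.47 (SE 0.08). Also higher, and chosen after their values were seen, were the purine receptor P2ry12 (0.56), the microglial surface marker Tmem119 (0.40), the receptor Csf1r (0.33) and the TGF-beta receptor Tgfbr1 (0.52); P2ry12 lost its call in 12 of 20 alternatives, among them without WT13, WT16 and WT17 (0.39, edgeR adjusted p = 0.507). The 2 members that fell were Gpr84, a fatty acid receptor, at a log2 fold change of -1.86 (SE 0.14), and Ltc4s, leukotriene C4 synthase, at -0.90 (SE 0.12). The median over the list was 0.34. Without WT13, WT16 and WT17, 10 of the 13 genes remained higher and the median was 0.20.

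The disease-associated microglia list had 3 higher and 6 lower of 27 measured genes, or 3 and 7 adjusted over the list alone, with a median of -0.12. As a whole the list did not pass (limma's camera, adjusted p = 0.76 with an estimated correlation). The median was -0.23 without WT13, WT16 and WT17 (2 higher and 6 lower), -0.22 with the marker covariate, -0.20 with library totals and -0.21 without cKO2. The genes that fell included the lipid carrier Apoe, from 2086 ± 178 CPM (n = 6) to 1044 ± 248 CPM (n = 5; log2 fold change -1.0, SE 0.12; edgeR adjusted p = 7.36e-05), the lysozyme Lyz2 (-1.20, SE 0.15), the surface glycoprotein Cd52 (-1.67, SE 0.11) and the chemokine Ccl6 (-0.62, SE 0.10). The remaining genes past the threshold, chosen after their values were seen, were Cd68 and Fabp5, which fell, and Ctsb, Ctsd and Timp2, which rose; Cd68, Fabp5 and Timp2 lost their calls in 8, 10 and 11 of 20 alternatives. Axl, Itgax, Clec7a and Cst7, markers of the same state chosen after their values were seen, had log2 fold changes of -0.29, -0.28, -0.35 and -0.23 and did not pass. These do not stand for the list: other members that did not pass leaned up. In all, 10 of the 27 measured genes had a positive log2 fold change. Trem2 lies in a stretch with no counts.

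Of 25 measured interferon response genes 4 fell in cKO and none rose, and the list did not pass limma's camera test with an estimated correlation (adjusted p = 0.60). Adjusted over the list alone 14 fell, and the median log2 fold change was -0.74. The number that fell was 2 without cKO4 or without WT16, 6 without WT17 or with the marker covariate, and 8 with library totals. Ifit3 had a log2 fold change of -1.34 (SE 0.20), Ifit2 -1.39 (SE 0.31), Irf7, a regulator of interferon transcription, -1.14 (SE 0.29) and Ifit3b -2.34 (SE 0.59). Irf7 and Ifit3b each lost their call in 6 of the 20 alternatives computed for them. The adjusted p of the list was 1.2e-07 with a preset correlation (limma's camera) and 0.023 with fry, which tests whether the genes move one way on balance. Without WT13, WT16 and WT17 the median was -0.91 and 3 genes fell, 2 of them among the 4.

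**Figure D3:**
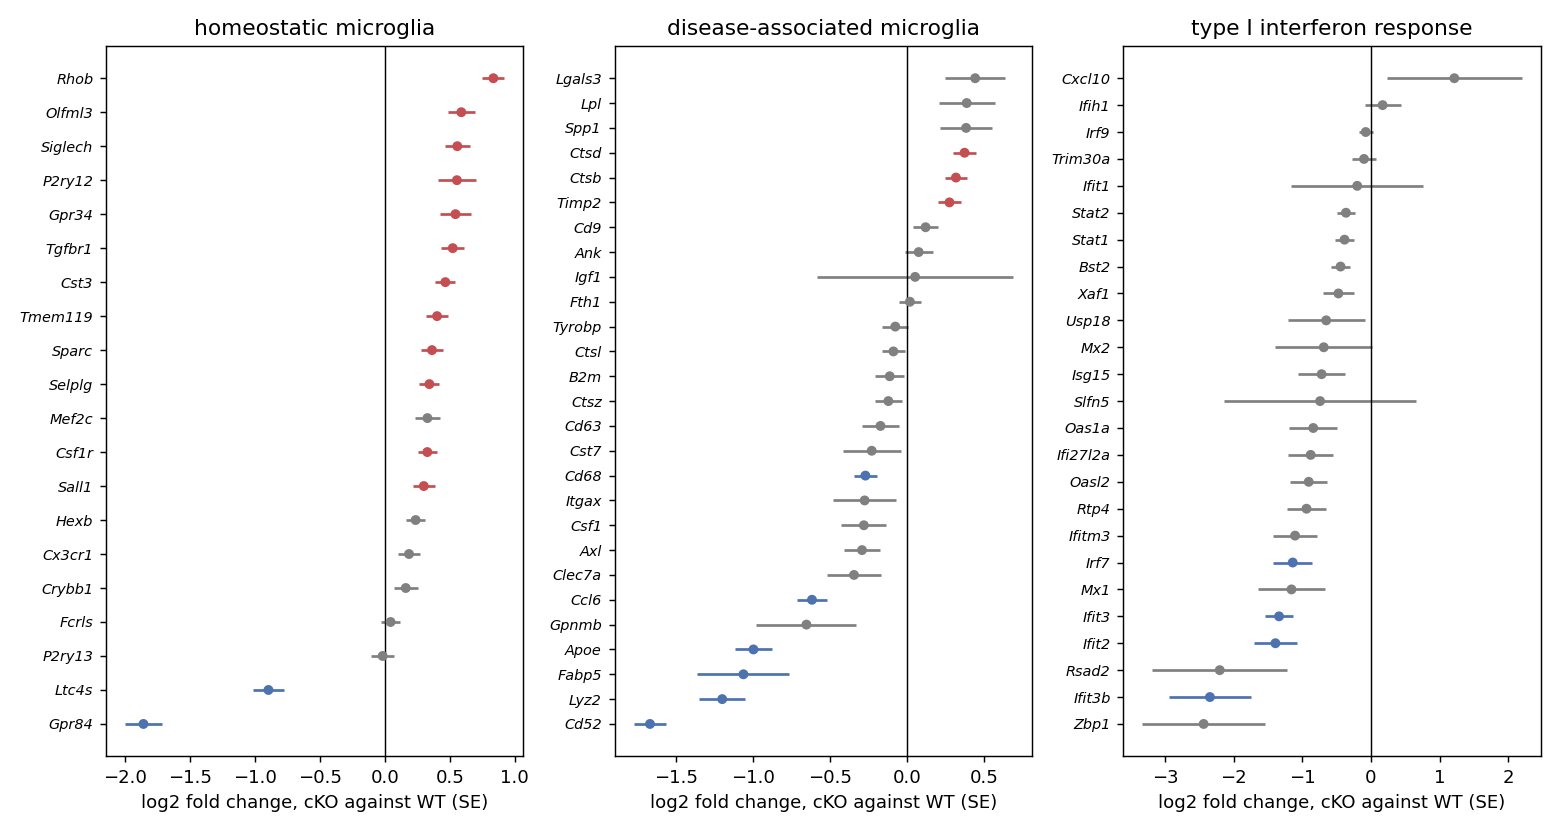
Log2 fold change of cKO against WT with its SE for measured genes of 3 lists; red is higher and blue lower past the threshold, and grey did not pass. In the homeostatic list 12 of the genes drawn are red and 2 blue, in the disease-associated list 3 and 6, and in the interferon list 0 and 4.

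Among other immune lists, Tlr2, a sensor of bacterial lipoproteins (-0.63, SE 0.09), and the cytokine Il1a (-0.77, SE 0.18) fell and the chemokine Ccl3 (0.56, SE 0.15) rose, out of 21 genes of the inflammatory list; Ccl3 lost its call in 8 of 20 alternatives. The co-stimulatory ligand Cd80 fell (-1.07, SE 0.25), 1 of 6 measured genes of the MHC class II list, and H2-T23 fell (-0.45, SE 0.11), 1 of 7 of the class I list; 9 of 15 genes listed for class II and 7 of 15 for class I had 0 counts in every library. H2-T23 did not pass without cKO4 or cKO7. In the complement list C1qb rose (0.37, SE 0.08), 1 of 12. In the lysosome and phagocytosis list 3 of 23 rose, the receptor Mertk (0.62, SE 0.11), Ctsa (0.34) and Psap (0.33), and 2 fell, Ctsc (-0.40, SE 0.08) and Man2b1 (-0.31), the latter chosen after its value was seen and lost in 6 of 20 alternatives. Plin2, a lipid droplet protein (0.68, SE 0.13), and Pltp (0.38, SE 0.09) rose among 22 genes of cholesterol and lipid handling; Pltp overlaps Ctsa in the annotation, so reads can be shared, and lost its call in 5 of 20 alternatives.

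Of 20 immediate early and stress genes 4 rose, namely Klf2, Klf4, the heat shock co-chaperone Dnajb1 (0.75, SE 0.11) and Klf6 (0.49, SE 0.11), and none fell. Pfkfb3, a regulator of glycolysis, fell (-0.52, SE 0.08), 1 of 17 glycolysis genes, and the receptor Il10ra rose (0.33, SE 0.08), 1 of 14 trophic and anti-inflammatory genes, and lost its call in 5 of 20 alternatives, among them without WT13, WT16 and WT17 (0.22, edgeR adjusted p = 0.154). Among 19 genes of the H3K27 and H3K4 methylation machinery, Eed, a subunit of the complex that methylates H3K27 (0.71, SE 0.16), and Bmi1 (0.61, SE 0.15) rose and the H3K4 methyltransferase Kmt2d fell (-0.41, SE 0.12). Kmt2d lost its call in 12 of 20 alternatives, and none of the 3 passed without WT13, WT16 and WT17. Eed, Bmi1 and Kmt2d were then at log2 fold changes of 0.64, 0.42 and -0.21 (edgeR adjusted p = 0.0712, 0.185 and 0.411). No gene passed among 28 of oxidative phosphorylation (Atp5b 0.11, Sdha -0.02), 29 ribosomal protein genes (Rpl4 0.12, Rpl8 0.12), 21 cell cycle genes (Mcm3 0.07, Mcm6 0.05) or 10 genes that escape X inactivation (Ddx3x 0.0009, Kdm5c 0.02). Xist, on the last of these lists and chosen after its value was seen, was at -1.61 (SE 0.44, edgeR adjusted p = 0.0799). Adjusted over that list alone, 1 gene was higher and 1 lower.

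Some markers of other spinal cord cells differed between libraries rather than between all samples of each genotype. Xist, a nuclear RNA on none of their lists, differed between libraries and also, except for WT15, between the genotypes. It was at 7.38, 7.44 and 7.94 log2 CPM in WT13, WT16 and WT17 and at 6.34, 6.24 and 5.72 in WT8, WT9 and WT15. In cKO it ran from 4.65 to 5.85. The axonal gene Nefh was at 937.1, 723.2 and 1240.7 CPM in WT13, WT16 and WT17 and between 258.9 and 428.0 elsewhere. Other markers did not follow this split: the oligodendrocyte gene Mbp was lowest in WT16 (2809.35 CPM), and the mean of the fibroblast list was lowest in WT13 (1.33 log2 CPM). Pmp22 and Il7r, also on marker lists, did not overlap between the genotypes. Pmp22 ran from 594.76 to 641.21 CPM in cKO and from 452.66 to 568.88 in WT. Il7r ran from 2.12 to 9.94 CPM in cKO and from 11.47 to 15.16 in WT. Xist averaged 5.38 ± 0.48 log2 CPM in cKO (n = 5) and 6.84 ± 0.86 in WT (n = 6; exact permutation p = 0.0108, adjusted 0.054 over 10 measures). The 10 most abundant genes took 11.9 ± 0.2% of counts in cKO and 10.1 ± 0.8% in WT (exact permutation p = 0.00216, the smallest possible, adjusted 0.0216). The labels name no batch that these libraries share.

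The marker lists gave medians of -0.26 over 21 neuronal genes (Nefh -1.0, Nefm -0.43), -0.12 over 17 astrocyte genes (Atp1b2 -0.04, Gfap -0.39) and -0.05 over 18 oligodendrocyte genes (Mbp -0.0004, Mobp 0.07), with no gene past the threshold. One of 13 oligodendrocyte precursor genes fell, Cspg4 (-1.09, SE 0.30, lost in 12 of 20 alternatives), with a list median of -0.23. Of 16 endothelial genes Pecam1 fell (-0.58, SE 0.14, lost in 4 of 20 alternatives). Without WT13, WT16 and WT17, where it was lost, Pecam1 was at -0.52 (edgeR adjusted p = 0.0669). The endothelial list, with a median of -1.01, passed limma's camera test with a preset correlation (adjusted p = 0.005) but not with an estimated one (adjusted p = 0.66). No gene passed in the lists of pericytes (8 genes, median -0.87; Vtn -0.76, Rgs5 -1.34), fibroblasts (13, -0.02; Igf2 -0.02, Col1a1 -0.10), Schwann cells (5, -0.79; Pmp22 0.24, Drp2 -0.79), border-associated macrophages (4, 0.34; Maf 0.33, Stab1 0.18), monocytes and neutrophils (3, -1.03; Fn1 -0.43, Vcan -1.03), lymphocytes (3, 0.23; Cd79b 0.23, Il7r -0.84) or erythroid cells (4, 0.60; Bpgm -0.08). Without WT13 Rgs5 was at -0.70 and Vtn at -0.43, without WT8 Vcan was at -0.44, and without WT17 Fn1 was at -0.16. Of these and the genes above that did not pass and had alternatives computed, Maf passed in 5 of 20 alternatives, Pmp22 in 3, and Il7r and Mobp in 1 each. None of the 29 lists passed with an estimated correlation, 3 passed with a preset one and 1 with fry. The median, mean and test differed in sign for the MHC class II, complement, lysosome, ribosomal protein, immediate early, X-escape and fibroblast lists.

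The first principal component held 22.4% of the variance, with the cKO libraries between -52.81 and -16.51 and the WT libraries between -12.06 and 137.28. The genotypes did not overlap on it (exact permutation p = 0.0108, adjusted 0.0325 over 3 components), but the gap was small beside the spread within WT. Highest on this component were WT13 (137.28), WT17 (35.3) and WT16 (10.69), the libraries with the highest mean of the neuron, astrocyte and oligodendrocyte markers. The second held 15.1% and did not pass (exact permutation p = 0.113, adjusted 0.169). The first no longer passed when any single cKO library was left out (adjusted exact permutation p from 0.10 to 0.143), and it passed without any single WT library.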

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

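The tests on Olfml3, Tef, Bhlhe41, Ccrl2, Cd33, Adrb1 and the library measures were chosen after the data were seen. Of 338 groups tested, 21 held a library whose gap to its nearest neighbour, divided by the group's range, passed Dixon's 95% critical value, where chance gives about 1 in 20, or 16.9; values are log2 CPM. In WT13, Klf4 was high (3.55 against 2.25 to 2.58, gap ratio 0.746), and Tsc22d3 (6.56 against 7.27 to 7.61, 0.671) and Cd33 (7.32 against 7.81 to 7.93, 0.799) were low. In WT8, Pstpip1 was low (0.688) and Adrb1 high (0.648). WT16 was low for Apoe (10.78 against 11.00 to 11.13, 0.642), and WT17 was high for Tef (0.634).

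In cKO2, Mcm3 (0.839) and Pfkfb3 (0.723) were high, and Adrb1 (0.719) and the oligodendrocyte list mean (0.750) were low. In cKO4, Neat1 was high (7.49 against 6.79 to 6.94, 0.786) and Ccrl2 low (0.732). In cKO5, BC147527 (0.742) and the interferon list mean (2.55 against 1.96 to 2.11, 0.746) were high. In cKO6, Pecam1 (0.729) and Olfml3 (0.783) were high, and Pstpip1 (0.804), Pmp22 (0.722) and Bhlhe41 (0.770) low. Ddx3x was low in cKO7 (6.70 against 7.18 to 7.36, 0.734), the library with the fewest Kdm6a CPM.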

How the results depend on the processing

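Leaving out WT13, WT16 and WT17 and halving the counts were chosen after the data were seen. No paired analysis was possible because the groups share no replicate numbers. Genes higher and lower in cKO numbered 298 and 389. The 2 counts differed by over 1.5 times, for at least one direction, with library totals (601 lower), a threshold of 0.1 (510 and 632), a 1.5-fold limit (83 higher), DESeq2 (516 and 716) and without the 3 WT libraries (164 higher). Leaving out single libraries gave 170 to 388 higher (170 without cKO5, 173 without cKO6) and 264 to 557 lower. Kdm6a kept its sign and did not pass in any setting run. Lists that passed numbered 3 with a preset correlation and 1 with fry, against 0. The adjusted principal component p ranged from 0.0238 to 0.143 (first) and 0.1 to 0.437 (second) on leaving out single libraries. For the 95 named genes past the threshold, 924 of 1045 leave-one-out values and 797 of 855 others stayed past it, and none changed sign. These genes were chosen among those that passed. Of all 687 genes past the threshold, 417 (without cKO5) to 638 (without WT15) stayed past it on leaving out single libraries. The cause was not tested for the values below, all of genes and lists that did not pass. Both mates counted as 2 would make low counts less precise than they look, and genes near the filter are limited by depth.

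Signs that changed, as log2 fold changes: Ddx3x -0.0025 with DESeq2's size factors and with DESeq2. Library totals: Mcm3 -0.014, Mcm6 -0.029, Ddx3x -0.085, Kdm5c -0.067, Mobp -0.019, Lta4h -0.075. Covariate: Sdha 0.016, Mcm3 -0.0036, Mcm6 -0.12, Ddx3x -0.045, Atp1b2 0.038, Mbp 0.088, Igf2 0.10, Col1a1 0.12, Fn1 0.11. Limma-voom: Sdha 0.012, Mcm6 -0.055, Ddx3x -0.00048, Mbp 0.051, Igf2 0.056, Col1a1 0.089, Fn1 0.072. Without the 3 WT libraries: Sdha 0.027, Rpl4 -0.016, Mcm3 -0.0058, Mcm6 -0.13, Nefm 0.013, Atp1b2 0.062, Mbp 0.055, Vtn 0.011, Igf2 0.0049, Col1a1 0.012, Drp2 0.061, Fn1 0.098, Cd79b -0.038, Arntl -0.018. Single libraries left out: Sdha -0.049 to 0.013, Mcm3 -0.031 to 0.13, Ddx3x -0.050 to 0.099, Mbp -0.039 to 0.055, Igf2 -0.22 to 0.092, Mcm6 -0.087 to 0.20, Col1a1 -0.27 to 0.19, Kdm5c -0.056 to 0.049, Lta4h -0.070 to 0.11, Arntl -0.012 to 0.24.

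Lists that changed direction in limma's camera test, with adjusted p: Schwann cell 0.93 with library totals; with the covariate, astrocyte 0.98 and MHC class I, cell cycle, trophic factors, oligodendrocyte and Schwann cell 0.78; without the 3 WT libraries, lysosome and ribosomal proteins 0.92 and MHC class I, cell cycle, trophic factors, neuron, astrocyte, oligodendrocyte and Schwann cell 0.83. With single libraries left out the ranges were 0.72 to 0.97 for cell cycle, 0.72 to 0.94 for trophic factors and 0.70 to 0.98 for Schwann cell.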

Other observations

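Chosen only after the results were seen were the 8 gene lists and the genes named in this part, the test of sampling noise on Kdm6a, the test of Kdm6a with the marker covariate, and the test of dilution on the disease-associated list. Set tests of these 8 lists are therefore not independent evidence. The covariate test replaced a rank correlation within the cKO group that was dropped because 5 libraries are too few, and the covariate fit existed by then.

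Of 6 Fc gamma receptor genes 4 fell in cKO: Fcgr4 (log2 fold change -2.24), the neonatal Fc receptor Fcgrt (-1.0), the inhibitory receptor Fcgr2b (-0.55) and Fcgr1 (-0.38); the list did not pass limma's camera test with an estimated correlation (adjusted p = 0.20). Of 11 eicosanoid genes Alox5, the 5-lipoxygenase (-2.03, SE 0.17), its partner Alox5ap (-0.72) and Ltc4s (-0.90) fell, and Hpgd, which breaks down prostaglandins, rose (0.43, lost without cKO6 with edgeR adjusted p = 0.054), and the list did not pass (adjusted p = 0.30). These are 3 genes of leukotriene synthesis, whereas Lta4h, at 0.01, did not pass. Among 8 Siglec genes Siglecf (-2.33) and Siglece (-0.87) fell and Cd33 (0.76) and Siglech (0.56) rose, and the list did not pass (adjusted p = 0.30). With a preset correlation the Fc gamma, eicosanoid and Siglec lists passed (limma's camera, adjusted p = 2e-05, 0.0071 and 0.047). They also passed with fry (adjusted p = 0.00074, 0.0034 and 0.012). Without WT13, WT16 and WT17, 5 of the 6 Fc gamma genes were lower, and 4 of the 11 eicosanoid genes were lower and 1 higher.

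Of 15 genes of purine and adrenergic receptors and ion channels 3 fell and 4 rose, and the list did not pass limma's camera test with an estimated correlation (adjusted p = 0.75). The adenosine receptor Adora3 (-1.11, SE 0.12), P2ry6 (-0.52) and P2rx4 (-0.45) fell, and among those that rose were the adrenergic receptor Adrb1 (1.23, SE 0.14), the purine receptor P2ry12 (0.56) and the potassium channel Kcnk6 (0.42); P2rx4 and P2ry12 lost their calls in 7 and 12 of 20 alternatives. Without WT13, WT16 and WT17, 2 genes of this list rose and 4 fell, and Kcnk6 did not pass (0.27, edgeR adjusted p = 0.0663). Among 10 Toll-like receptors Tlr7 rose (0.85) and Tlr2 (-0.63) and Tlr9 (-0.66) fell, and the list did not pass (adjusted p = 0.78). Of 9 chemokine receptor genes 2 rose, among them Cmklr1 (0.68), and Ccrl2 fell (-0.84), and the list did not pass (adjusted p = 0.48). Ccrl2 lost its call in 6 of 20 alternatives, among them without the 3 WT libraries (-0.89, edgeR adjusted p = 0.0516). The receptor and channel, Toll-like receptor and chemokine receptor lists did not pass with a preset correlation either (limma's camera, adjusted p = 0.4, 0.56 and 0.18). Nor did they pass with fry (adjusted p = 0.59, 0.59 and 0.25).

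The 687 genes exceeded what other groupings gave: 1 of the 100 splits of the samples drawn, the real one, called as many, and the highest of the others called 8. The other splits mixed the genotypes, which puts any genotype difference within their groups and lowers their calls. The comparison cannot address a batch or carry-over that follows genotype.

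Kdm6a RNA was 65.7% of WT in cKO by the fitted fold, and 2 technical explanations stay open. Sampling noise hiding a loss of 90% was argued against, since the lower end of the 95% interval was -1.12, a loss of far less than 90%. Reads from exons outside the deleted part may keep the gene count up, which needs counts per exon. Undeleted RNA of other cells may add to it: with the covariate the log2 fold change was -0.66 (interval -1.22 to -0.11), too wide to decide. Such RNA carried at a similar level by all libraries would in any case escape the covariate, which follows only differences between libraries. Incomplete deletion, which the design allows, was not tested.

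In cKO 13 of 21 homeostatic genes were higher and 4 of 25 interferon genes lower, although neither list passed limma's camera test with an estimated correlation (adjusted p = 0.66 and 0.60). WT13, WT16 and WT17 had the highest mean of the neuron, astrocyte and oligodendrocyte markers (6.01, 5.75 and 6.15 log2 CPM, against 5.43 to 5.68 elsewhere), WT16 by the least. Carry-over of interferon genes in those libraries was argued against: without them the median was -0.91 (bootstrap interval over genes -1.09 to -0.44). The interferon list mean was 2.93, 2.92 and 3.46 log2 CPM in WT8, WT9 and WT15, against 1.96 to 2.55 in cKO. Dilution of microglial RNA in WT13, WT16 and WT17 may explain part of the homeostatic shift. The homeostatic median went from 0.34 to 0.20 (0.10 to 0.31) without them, at the edge of the bound set at 0.2. Dilution should also lower the disease-associated genes in WT, but their median of -0.12 (-0.28 to 0.05) did not settle this. The bootstrap intervals treat genes as independent and do not measure the spread between samples. Loss of Kdm6a is the biological explanation in the design, and it stays a hypothesis.

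Ddit4, Tsc22d3, Klf2 and Klf4 rose together with Sgk1 (0.98), several of them known targets of glucocorticoids. Higher glucocorticoid signalling in the cKO animals may account for this, but the values did not settle it. Of 19 glucocorticoid-induced genes 4 rose and 1 fell (2 and 1 without WT13, WT16 and WT17). The list did not pass with an estimated correlation (limma's camera, adjusted p = 0.34) or with fry (adjusted p = 0.2). With a preset correlation it passed (limma's camera, adjusted p = 0.0071). Its genes other than Ddit4, Tsc22d3 and Sgk1 had a median of 0.14 (bootstrap interval over genes 0.03 to 0.43). Of these Mertk rose (0.62) and Tgm2 fell (-2.73). A different time of day at collection may also account for the rise: 5 of 16 clock output genes passed. Per2 (-1.42), Dbp (-0.62, interval -0.95 to -0.29), Tef (-0.45) and Bhlhe41 (-0.68) were lower and Nfil3 (0.73) higher. As a whole the clock list did not pass with an estimated correlation (limma's camera, adjusted p = 0.30). It passed with a preset one (limma's camera, adjusted p = 0.047) and with fry (adjusted p = 0.025). Per2, Dbp and Nfil3 lost their calls in 5, 6 and 9 of 20 alternatives, and without the 3 WT libraries 3 passed (Dbp, Tef and Bhlhe41). Arntl (0.10), Clock (0.16) and Npas2 (-0.25), expected to move opposite to Per2, Dbp and Tef if time of day were the cause, did not pass. Per1, at 0.94, opposite to Per2, did not pass in the main test but did in 4 of 20 alternatives (1.14, edgeR adjusted p = 0.00112 without cKO2). Neither can be told apart from genotype, because the labels give no collection time and no hormone measurement. Within cKO the rise was uneven. Ddit4 was at 70.62 and 80.43 CPM in cKO2 and cKO4 and at 229.84, 321.3 and 384.79 in cKO5, cKO6 and cKO7. Klf4 in cKO2 (7.76 CPM) lay below WT13 (11.63). The glucocorticoid list mean was 5.05, 5.31, 5.67, 5.96 and 5.99 log2 CPM in these cKO libraries, and 5.14 to 5.37 in WT. Ddit4 and Klf2 were above every WT library in each cKO library.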
